A study of Mus musculus with 42 samples.

How the data were processed

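Reduced representation bisulfite sequencing (RRBS), which reads the methylation of cytosines in restriction fragments rich in CpG, was deposited for 42 samples from Dnmt3a-null mouse malignancies and wild-type control cells. The samples fell into 21 libraries with values of their own, from 20 combinations of mouse and cell type. In 7 cases the labels of 4 technical replicates named the same deposited table, which was therefore taken as 1 library for that mouse. T-ALL mouse 2 had 2 technical replicates, converted with different bisulfite kits per the labels, and their counts were summed. The groups were AML (4 mice), MDS (4), T-ALL (3), ETP (1), and wild-type LSK cells (3), Gr1+ granulocytes (2) and CD4+CD8+ thymocytes (3). Per the labels, the wild-type libraries came from primary transplant controls 1, 2 and 3, so that several cell types shared a control animal.

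Per the submitters' processing notes, bisulfite reads were aligned with BSMAP 2.74 to the mouse genome build mm9. Per the file headers, each listed cytosine carried the deposited counts of unconverted reads and of all reads, with no normalization. The deposited ratio was a fraction, the unconverted reads over all reads of the cytosine, and recomputing it gave the listed value to the printed decimals in every library. Listed cytosines had at least 5 reads in every library, and a cytosine with fewer reads was therefore unknown, not unmethylated. At most 71 cytosines of a library sat at a shared highest count, so their true depth is unknown. Every listed position matched a cytosine of the expected strand in the mm9 sequence (100% in each library).

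Counts of both strands of a CpG were summed, and autosomal CpGs with at least 10 reads were used. Methylation of cytosines outside CpG served as the measure of incomplete conversion. The mean level of a library was the unweighted mean over the 169863 CpGs that passed this minimum in every library except ETP, whose depth was lower. Tiles were 500 bp long and needed at least 3 such CpGs in every library of a comparison. Promoters were regions of 1000 bp either side of each annotated transcription start, with overlapping regions of a gene merged, and needed at least 5 such CpGs. Gene positions came from an annotation of the same build, and 41449 promoter regions were annotated. Tiles with up to 9 CpGs in the reference were called low density, those with up to 24 medium density and the others high density. Reads without molecular identifiers are not independent molecules, so the precision that depth gives covers counting error only.

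Each tile or promoter was tested with a logistic model across mice on methylated and unmethylated counts. Libraries were weighted by N/(1 + (N - 1) rho), where N is the reads of the region and rho is a single estimate per comparison. The dispersion per region was moderated with a port of the limma function squeezeVar, checked against limma 3.58.1. A quasi-F test, two-sided, gave p-values that were adjusted over all regions tested by the Benjamini-Hochberg method. Called regions had an adjusted p under 0.05 and a difference of group means of at least 20 percentage points. Only the libraries of the groups compared entered each fit, and the comparison of the AML and T-ALL effects used an interaction term. Unless another tool is named, an adjusted p is from this limma-moderated model. Mean levels were compared with exact permutation tests, two-sided, adjusted over the 9 comparisons of each measure. Gene lists were compared with the other measured genes by Fisher's exact test, adjusted over the 36 tests of 12 lists in 3 comparisons for each direction.

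Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, per main comparison, the 8 promoters with the largest loss and the 8 with the largest gain among called promoters whose groups did not overlap. It also named the 5 tiles of each direction under the same condition, and up to 3 called promoters from each list. Dnmt3a, Cdkn2a, Notch1, Kit, Hoxa9 and Meis1 were always named where measured. For T-ALL, 1 tile and 1 promoter that the rule named are not described. The lists were HSC regulators, myeloid, T lineage, Notch pathway, B lineage, erythroid and megakaryocytic, imprinted, germline, developmental transcription factors, tumour suppressors, leukaemia drivers and DNA methylation machinery. The myeloid, T lineage, B lineage and erythroid and megakaryocytic lists stood for cell types that whole marrow or thymus can hold.

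Alternatives were the read minimum, the CpG minimum, tile length, promoter width, the difference and adjusted p thresholds, rho at 0 or 1, and leaving out each library. Others were single technical replicates, the batch, a replicate block, limma on log2 ratios of counts, and the quasi-likelihood test of edgeR 4.0.16. The batch is the deposit batch, inferred from the labels: libraries with a table of their own (the first batch) against those whose table stood for 4 technical replicates (the second batch). Shared transplant controls paired the wild-type cell types, and the correlations of their deviations from the group means lay between 0.151 and 0.300 for thymocytes and LSK cells, and between 0.009 and 0.031 for granulocytes and LSK cells. AML and MDS mice of the same number also deviated together (correlations of 0.231 to 0.528), although only 2 of the 4 pairs correlated best with their own number, and those numbers follow the deposit batch. The numbers of the other comparisons did not pair the libraries.

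The model was tested on simulated data with the real depths and estimated spread. Changes of 30 and 60 points were recovered in 49.0% and 70.2% of changed tiles for AML against LSK cells (26565 tiles), 45.0% and 81.6% for MDS (29459 tiles) and 12.0% and 60.2% for T-ALL against thymocytes (41745 tiles). In data simulated without change, 6.48%, 6.94% and 6.82% of tiles had an unadjusted p under 0.05, so the p-values ran slightly small, and 0, 4 and 1 tiles were called. The simulated tiles had the same dispersion in both groups and no shift shared by a whole library or batch. In low density tiles the SD over mice was 12.5 in AML and 6.16 in MDS, against 1.39 and 1.38 in LSK cells. The simulated rates may therefore not hold for the real data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3. Sex chromosomes were left out of the comparisons, ETP was left out of all tests because it had 1 mouse, and no reads were realigned because only tables of cytosines were used.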

Results

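DNA methylation was measured by RRBS in malignancies that arose after transplantation of Dnmt3a-null haematopoietic stem cells, and in matched wild-type cells. Dnmt3a is a DNA methyltransferase that places methyl groups on unmethylated CpGs. The Dnmt3a-null libraries came from bone marrow of mice with acute myeloid leukaemia (AML, 4 mice) or myelodysplastic syndrome (MDS, 4 mice), and from thymus of mice with T-cell acute lymphoblastic leukaemia (T-ALL, 3 mice). A single further mouse carried the disease label ETP. Wild-type controls were sorted LSK cells, which hold the stem and early progenitor cells of the marrow (3 libraries), Gr1+ granulocytes (2 libraries) and CD4+CD8+ thymocytes (3 libraries, called WT T cell in the plots). Reads at CpGs ranged from 16169240 to 54467592 per library, with 6337032 in ETP. The median depth per listed CpG was 15 to 27 reads, with 11 in ETP, and 408320 to 717724 autosomal CpGs had at least 10 reads outside ETP, which had 225204. Methylation outside CpG lay between 0.0602% and 0.172% in all 21 libraries.

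The Dnmt3a gene on chromosome 12 (mm9, 3806007 to 3914443) was looked at first as a check of the genotype labels. It held 109 CpGs seen in at least 6 of the 8 wild-type libraries, and 0 of these were missing from every Dnmt3a-null library. Such CpGs lay in exons 1 and 23 (5 and 8 CpGs) and in no other exon, and the labels do not name the deleted exons. RRBS reads therefore could not check the deletion. The Dnmt3a promoter at 12, 3805007 to 3808160, was nearly free of methylation in all tests, at 0.146% ± 0.169 (SD, n = 4) in AML and 1.12% ± 1.93 (SD, n = 3) in LSK cells (adjusted p = 0.480), and at 0.394% ± 0.312 (SD, n = 4) in MDS (adjusted p = 0.576). It was at 0.585% ± 0.432 (SD, n = 3) in T-ALL and 0.615% ± 0.363 (SD, n = 3) in thymocytes (adjusted p = 0.976). A second Dnmt3a promoter (12, 3890728 to 3892744), measured only there, had 10.1% ± 4.33 and 7.34% ± 3.20 (adjusted p = 0.639).

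Mean CpG methylation lay in different directions from the matched control in the marrow diseases and in T-ALL. AML marrow had 22.8% ± 5.45 (SD, n = 4) and MDS marrow 23.0% ± 2.46 (SD, n = 4), against 28.3% ± 0.521 (SD, n = 3) in LSK cells. T-ALL thymus had 32.6% ± 2.00 (SD, n = 3) against 28.8% ± 1.54 (SD, n = 3) in thymocytes, and wild-type granulocytes had 21.8% ± 3.25 (SD, n = 2). In AML and MDS the gap in points was widest in CpG-poor DNA. Tiles of low density differed from LSK cells by -15.2 and -15.6 percentage points. Tiles of medium density differed by -7.11 and -6.86, and tiles of high density by -0.533 and -0.289. LSK cells had 69.7% in low, 39.9% in medium and 4.47% in high density tiles. Dense tiles therefore had little methylation to lose, and the gaps in points do not compare the losses relative to these levels. T-ALL showed the opposite layout, with 12.1% ± 1.41 (SD, n = 3) in high density tiles against 4.69% ± 0.518 (SD, n = 3) in thymocytes, and differences of 2.435 points in medium and -3.52 in low density tiles.

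The differences in mean level were -5.46 points for AML (exact permutation p = 0.0571), -5.33 for MDS (exact p = 0.0571) and 3.74 for T-ALL (exact p = 0.1). In each of these the groups did not overlap, each p was the smallest its design allows, and after adjustment they were 0.257, 0.257 and 0.300. For granulocytes the difference from LSK cells was -6.52 points (exact p = 0.2, also the smallest possible). The 11 Dnmt3a-null mice together differed from the 3 transplant controls by -1.61 points (exact permutation p = 0.665). Each control was the mean of its cell types, while the null mice were marrow or thymus. The opposite differences of marrow and thymus offset each other in this pool, so it does not show the absence of a genotype difference. Within the first and the second deposit batch the differences were -9.10 and -1.77 points for AML, -7.37 and -3.24 for MDS, and 4.98 and 1.25 for T-ALL. The first batch held 2 libraries of each of these groups and controls. The second held 2 AML, 2 MDS, 1 T-ALL, 1 LSK and 1 thymocyte library, so its differences rest on 1 control library each. AML mouse 2 had the lowest level (15.0%), and without it the AML difference was -2.86 points.

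**Figure D1:**
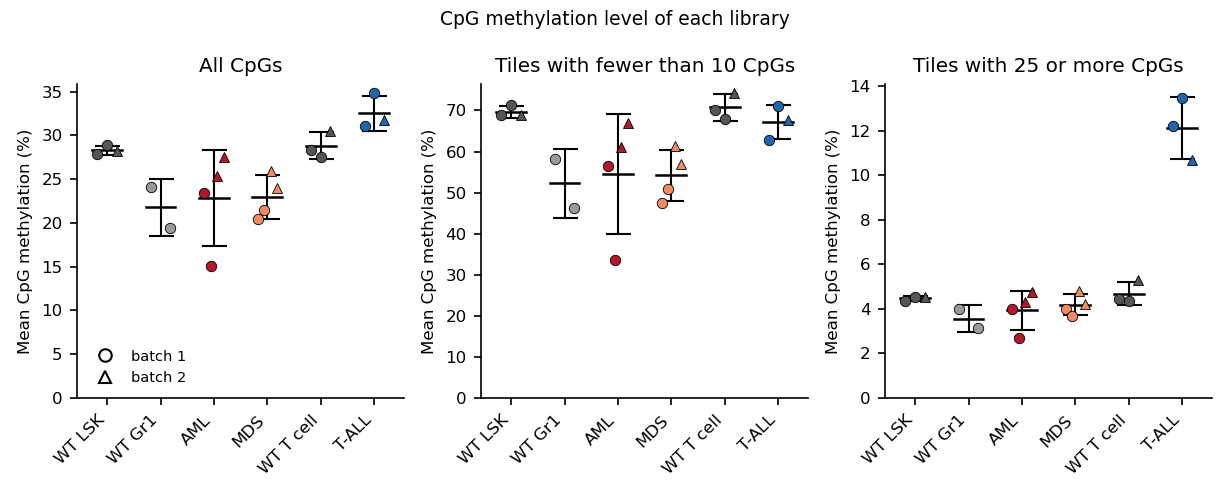
Mean CpG methylation (%, vertical axis) of each library by group, over all CpGs and over tiles with fewer than 10 or with 25 or more CpGs. Points are libraries (circles, first deposit batch; triangles, second), and bars give the mean and SD; in CpG-dense tiles the T-ALL libraries have a mean of 12.1% against 4.69% in thymocytes.

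AML marrow was compared with LSK cells, the wild-type stem and progenitor control. Introns had 47.3% ± 10.1 methylation (SD, n = 4) in AML and 58.3% ± 1.03 (SD, n = 3) in LSK cells, while promoter tiles had 4.93% ± 1.22 and 6.05% ± 0.200 in the same libraries. Hoxa9, a homeobox gene of stem cells and myeloid leukaemia (6, 52179264 to 52182088), had 1.69% ± 0.425 (SD, n = 4) in AML and 0.887% ± 1.26 (SD, n = 3) in LSK cells, with an adjusted p of 0.579. Its partner Meis1 (11, 18917717 to 18919961) had 0.740% ± 0.374 and 0.732% ± 0.556 in the same libraries (adjusted p = 1). The cell cycle inhibitor gene Cdkn2a (4, 88939523 to 88941557) had 0.685% ± 0.614 and 1.60% ± 1.01 (adjusted p = 0.470), and the receptor gene Notch1 (2, 26358342 to 26360344) had 0.371% ± 0.266 and 0.317% ± 0.374 (adjusted p = 0.942). Only promoter 1 of 2 of Meis1 and of Cdkn2a, and promoter 3 of 6 of Notch1, were measured in the 3 main comparisons. The values do not cover the other promoters of these genes.

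Among 26565 tiles, 0 were called lower and 0 higher in AML by the limma-moderated model, by limma on log2 ratios and by edgeR, and the first batch alone gave 2 lower. At an unadjusted p under 0.05 and at least 20 points, 910 tiles were lower and 4 higher (limma, 1415 and 4; edgeR, 866 and 1). Without regard to a test, 2033 tiles lay at least 20 points below LSK cells and 17 above, and the groups did not overlap in 11.5% of tiles, where chance gives 5.71%. Of 9471 promoters 0 were called by the model and by limma, with 31 lower and 0 higher at an unadjusted p under 0.05 in each.

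In every gene list, 0 promoters were called in AML, and 0 adjusted over the list alone. The lists had these numbers of measured genes: 18 HSC regulators, 6 myeloid, 5 T lineage, 19 Notch pathway, 2 B lineage, 3 erythroid and megakaryocytic, 11 imprinted, 3 germline, 33 developmental transcription factors, 23 tumour suppressors, 15 leukaemia drivers and 10 genes of the DNA methylation machinery. Median differences from LSK cells were taken over promoter regions, so a gene with several counted more than once. They were -12.5 points for the germline genes, which are methylated in most somatic cells, and -6.17 for the imprinted genes. For the myeloid markers the median was -2.04, and for the developmental transcription factors it was 0.371.

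MDS marrow had lower methylation than LSK cells at 272 tiles and higher methylation at 1, mostly in introns and between genes. Tsc22d1, which encodes a transcription factor of the TSC22 family, fell at an intronic tile (14, 76896001 to 76896500) to 25.4% ± 15.5 (SD, n = 4) from 97.4% ± 2.41 (SD, n = 3) in LSK cells (adjusted p = 0.0398). A tile 2067 bp from Hspa8, the gene of a constitutive heat shock protein (9, 40606501 to 40607000), fell to 13.9% ± 9.27 from 85.6% ± 7.04 (adjusted p = 0.0357). A coding exon of Rin2 (2, 145686001 to 145686500) fell by 67.7 points (adjusted p = 0.0357). A tile in an intron shared by Slc7a5, which encodes an amino acid transporter, and Gm20388 (8, 124423001 to 124423500) fell by 66.1 points, and a tile 24883 bp from the calcium pump gene Atp2b4 (1, 135722501 to 135723000) fell by 66.6 points (adjusted p = 0.0366 and 0.0499). The tile that rose lay 8141 bp from the sodium channel gene Scn8a (15, 100884501 to 100885000), at 53.5% ± 1.10 (SD, n = 4) in MDS and 23.2% ± 3.62 (SD, n = 3) in LSK cells (adjusted p = 0.0305). In each of these 6 tiles all MDS mice lay beyond all LSK libraries, as the rule for naming them required.

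Of the 272 lower tiles, 35.3% lay in introns, 37.1% between genes and 10.7% at promoters, and 3 were of high CpG density. Among all tiles tested, 3825 lay in introns, 7220 between genes and 15792 at promoters, and 13604 were of high density. A mean level below 20% was found in 18422 of them, which left little room for a loss of 20 points. The test covered 29459 tiles; 2162 were lower and 3 higher at an unadjusted p under 0.05 and at least 20 points, and the groups did not overlap in 25.2% of tiles, where chance gives 5.71%. The calls were fragile. The edgeR test called 0 lower and 0 higher (1987 and 5 at an unadjusted p under 0.05), limma called 1004 and 1, and the count of lower tiles was 4 without MDS mouse 1, 4 without MDS mouse 2, 1 without MDS mouse 4, 0 without LSK library 1, 0 without LSK library 2 and 764 without LSK library 4. Each of the 6 named calls was lost in at least 5 of the 7 leave-one-out fits, with adjusted p up to 0.136. A term for the deposit batch gave 482 lower and 2 higher tiles, and the first batch alone gave 1018 and 8.

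Promoters of MDS marrow had 0 calls among 9816 tested (44 lower and 0 higher at an unadjusted p under 0.05), and limma called 3 lower. Hoxa9 had 2.14% ± 1.2 (SD, n = 4) at its first promoter in MDS (adjusted p = 0.443) and 2.95% ± 1.40 at its second (6, 52175150 to 52178369; adjusted p = 0.989). At the same promoters as in AML, Meis1 had 1.31% ± 1.02 (SD, n = 4, adjusted p = 0.577), Cdkn2a 0.838% ± 0.293 (adjusted p = 0.388) and Notch1 1.02% ± 0.572 (adjusted p = 0.333). All 12 lists had 0 called promoters, and 0 adjusted over the list alone, among 18 HSC regulators, 6 myeloid, 5 T lineage, 18 Notch pathway, 2 B lineage, 3 erythroid and megakaryocytic, 12 imprinted and 4 germline genes, 34 developmental transcription factors, 24 tumour suppressors, 16 leukaemia drivers and 11 genes of the methylation machinery. Over promoter regions, median differences were -10.0 points for the germline genes, -5.08 for the imprinted genes and -1.61 for the myeloid markers.

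The differences of AML and of MDS from LSK cells went together across tiles. Over 26055 tiles they correlated with r = 0.921, their covariance was 74.4, and 84.4% had the same sign. With every library simulated from the LSK mean, and the simulated LSK libraries shared, the values were 0.577, 17.99 and 64.5%. Tiles are not independent replicates, part of the excess may come from the shared controls, since 3 LSK libraries do not give 2 to each comparison, and the simulation leaves out the deposit batches that AML and MDS share. Compared directly, AML and MDS marrow had 0 lower and 0 higher tiles among 38691 by the model and by limma, with 14 lower and 15 higher at an unadjusted p under 0.05 (limma, 18 and 18). Their mean levels differed by -0.129 points (exact permutation p = 0.971).

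T-ALL thymus gained methylation at promoters and other CpG-dense DNA that thymocytes keep nearly unmethylated, and lost it at fewer places. Compared with thymocytes, 2353 tiles rose and 414 fell. Among the tiles that rose, 73.3% were of high CpG density and 68.1% lay at promoters, whereas 29 of the tiles that fell were of high density. Of the 41745 tiles tested, 18368 were of high density and 21652 lay at promoters. In low density tiles the balance was reversed, with 132 lower and 53 higher among 6237, and introns had 148 lower and 165 higher. A promoter tile of Apba2, an adaptor protein gene of neurons (7, 71647001 to 71647500), rose to 92.6% ± 1.86 (SD, n = 3) from 5.2% ± 2.62 (SD, n = 3), with an adjusted p of 0.00152. Tiles at the promoters of Asxl3 (18, 22502001 to 22502500) and Fam189a1 (7, 72301001 to 72301500) rose by 86.6 and 84.4 points. A tile 19792 bp from the developmental transcription factor gene Pax3 (1, 78213501 to 78214000) rose by 85.4 points.

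The named tiles that lost methylation in T-ALL lay at Runx1, Gata3, Pdcd1lg2 and Rbbp6. Runx1, a transcription factor of haematopoiesis, fell at a promoter and coding exon tile (16, 92695501 to 92696000) to 1.17% ± 0.930 (SD, n = 3) from 94.9% ± 2.48 (SD, n = 3) in thymocytes (adjusted p = 0.00152). The neighbouring Runx1 tile (16, 92696001 to 92696500) fell by 89.7 points. Gata3, a transcription factor of T cell development, fell at a promoter and coding exon tile (2, 9796001 to 9796500) to 2.91% ± 4.31 from 85.6% ± 9.06 (adjusted p = 0.00575). Coding exons of Pdcd1lg2, which encodes a ligand of the receptor PD-1 (19, 29511501 to 29512000), and of Rbbp6 (7, 130145001 to 130145500) fell, with differences of -93.3 and -86.0 points. The 10 tiles that the rule named, which had to separate all T-ALL mice from all thymocyte libraries, kept their calls without any single library.

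The test covered 41745 tiles, and the groups did not overlap in 26.3% of them, where chance gives 10%. Limma called 3119 higher and 561 lower tiles, and edgeR 2838 and 447. In single mice, 3695, 4514 and 3331 tiles lay at least 20 points above the highest thymocyte library, and 1782 did so in all 3 mice, which were set against the same libraries. Without thymocyte library 1, 2 or 3 the model called 779, 843 or 1155 tiles higher and 143, 196 or 154 lower, so each control library moved the counts by more than 1.5 times. The technical replicates of T-ALL mouse 2 differed by a mean of 0.466 points with an SD of 5.30 over 67528 tiles, and 0.798% of tiles differed by at least 20 points, against 13.1% to 16.2% between T-ALL mice.

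Tiles that rose in T-ALL had low methylation in every other group. They had 52.3% ± 4.88 (SD, n = 3) in T-ALL and 8.19% ± 1.13 (SD, n = 3) in thymocytes. In LSK cells they had 7.37% ± 0.83 (SD, n = 3), in granulocytes 5.53% ± 1.26 (SD, n = 2), in AML 7.61% ± 2.33 (SD, n = 4) and in MDS 8.40% ± 1.36 (SD, n = 4). ETP had 11.8% over the 1023 of these tiles it covered.

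**Figure D2:**
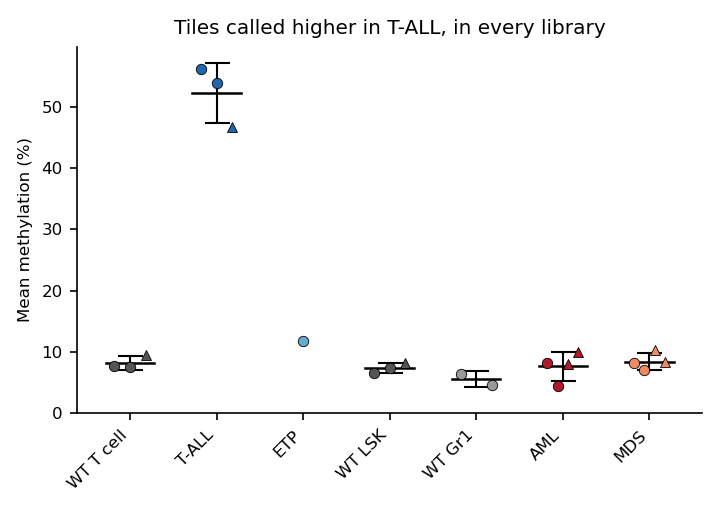
Mean methylation (%, vertical axis) of the 2353 tiles called higher in T-ALL, over those of them each library covered, by group (horizontal axis). Points are libraries (circles, first deposit batch; triangles, second), and bars give the mean and SD where a group has more than 1 mouse; T-ALL libraries lie between 46.8% and 56.2% and all others at or below 11.8%.

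At promoters, 1164 of 12497 regions (1115 genes) rose in T-ALL and 22 (22 genes) fell. Adcy2, an adenylate cyclase gene (13, 69137419 to 69139419), rose to 85.3% ± 5.47 (SD, n = 3) from 2.03% ± 0.899 (SD, n = 3), with an adjusted p of 0.000319. Fam19a5 (15, 87454660 to 87456660), Apba2 (7, 71645592 to 71648024), Wasf3 (5, 147195561 to 147197561), Gm9934 (7, 100228045 to 100230537) and Pxdn (12, 30621901 to 30623915) rose by 84.1, 82.7, 82.1, 81.9 and 79.6 points. The promoter of Gm16685 (3, 7611705 to 7613705) also covers the start of Il7, the gene of a cytokine that lymphocyte precursors need, and rose by 79.8 points (adjusted p = 0.00056).

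Promoters that fell included Fgr, a tyrosine kinase gene of myeloid cells (4, 132529010 to 132531017), at 0.194% ± 0.105 (SD, n = 3) in T-ALL and 46.2% ± 4.86 (SD, n = 3) in thymocytes (adjusted p = 0.000317). Mxra7 (11, 116688317 to 116690360) fell by 39.7 points (adjusted p = 0.000371). Scx (15, 76286868 to 76288868), BC028471 (5, 150169211 to 150172838), Rhd (4, 134419451 to 134421451), F630040L22Rik (9, 108006296 to 108008296), Ptpn14 (1, 191609512 to 191611551) and Bsn (9, 108011744 to 108013744) fell, with differences of -55.1, -52.5, -51.0, -39.6, -39.4 and -39.2 points. The calls of these last 6 promoters were each lost without at least 3 of the single libraries, with adjusted p up to 0.186.

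Developmental transcription factors formed the list with the most gains. Of 42 measured genes 20 rose and 0 fell (26 rose adjusted over the list alone), against 9.31% of the other genes (Fisher's exact test, adjusted p = 6.62e-09). In no list were the other genes matched for CpG density, although 9.39% of high and 0.85% of low density tiles rose. A gene counted if any of its promoters was called, and these 42 genes had 55 promoter regions, against 12497 for all 11804 genes. Genes of the same mice are not independent, so the Fisher p-values do not cover spread between mice. Nkx6-1, a homeobox gene of the pancreas and neural tube (5, 102093245 to 102095245), rose to 56.6% ± 22.3 (SD, n = 3) from 1.81% ± 1.32 (SD, n = 3). Isl1 (13, 117098896 to 117100896) and Foxd3, a factor of neural crest cells (4, 99321990 to 99323990), rose by 54.2 and 48.7 points. Without thymocyte library 1, 2 or 3 the list had 11 genes higher in each fit. Among tumour suppressors 10 of 27 rose (11 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00184). Sfrp1, an inhibitor of Wnt signalling (8, 24520974 to 24522974), rose to 80.01% ± 10.5 (SD, n = 3) from 5.26% ± 1.14 (SD, n = 3). The cadherin gene Cdh13 (8, 120806633 to 120808697) and the adhesion gene Cadm1 (9, 47337256 to 47339456) rose by 66.0 and 65.0 points.

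Gains in the lists of stem cell, myeloid, B lineage, erythroid and megakaryocytic genes and of leukaemia drivers were not separated from those of the other genes. Their shares were 15.8%, 16.7%, 50%, 33.3% and 5.56%, against 9.44% to 9.45% of the other genes (Fisher's exact test, adjusted p = 1 in each). Of 19 HSC regulators 3 rose (3 adjusted over the list alone): Meis1 rose to 26.9% ± 5.95 (SD, n = 3) from 1.57% ± 0.243 (SD, n = 3), with an adjusted p of 0.00189. Mecom rose at 2 promoters (3, 29909361 to 29913427 by 31.0 points, and 3, 30407409 to 30409744 by 24.4 points), and Fgd5 (6, 91927872 to 91929872) by 22.3 points. Of 6 myeloid markers 1 rose (2 adjusted over the list alone), the Fc receptor gene Fcgr3 (1, 172994066 to 172996066), by 54.8 points. Of 2 B lineage genes 1 rose (1 adjusted over the list alone), the B cell factor Pax5 (4, 44715285 to 44717878), by 26.0 points. Of 3 erythroid and megakaryocytic genes Ank1 rose at 3 promoters, the most by 24.99 points (8, 24084316 to 24086608), and Rhd fell (1 and 1 adjusted over the list alone). Among 18 leukaemia drivers 1 rose (1 adjusted over the list alone), Wt1 (2, 104965686 to 104968367), by 37.4 points. The myeloid list had 0 genes higher without T-ALL mouse 2 or without thymocyte library 1, 2 or 3, and 2 without T-ALL mouse 3. Leukaemia drivers had 0 without thymocyte library 1, 2 or 3, and the erythroid and megakaryocytic list 2 of 4 without T-ALL mouse 1 and 0 without thymocyte library 2.

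Imprinted genes, methylated at some regions on the copy from a single parent, had a median difference of 28.1 points over 18 promoter regions. These regions were annotated starts and were not chosen for methylation of a single copy. Of the 14 genes measured 3 rose (5 adjusted over the list alone; Fisher's exact p = 0.14, adjusted p = 1). Without T-ALL mouse 1 the list had 8 of 18 genes higher, and from 2 to 4 under the other alternatives. Grb10 rose at 2 promoters, to 63.4% ± 12.2 (SD, n = 3) from 8.33% ± 3.81 (SD, n = 3) at 11, 11936404 to 11939686, and by 48.9 points at 11, 11925327 to 11928974. Magel2 (7, 69520865 to 69522865) rose by 44.7 points and Plagl1 (10, 12809497 to 12812589) by 33.9. In contrast, 0 genes were called by their promoters, and 0 adjusted over the list alone, among 8 T lineage, 19 Notch pathway and 4 germline genes and 13 genes of the methylation machinery. The T lineage list held 28 genes and the germline list 25, so most of their genes were not measured. Promoter tiles of Gata3 (T lineage list) and Runx1 (HSC regulators) were called lower by themselves, although 0 genes of either list were lower by whole promoter regions. The Notch pathway had 1 gene lower without T-ALL mouse 2 and 1 higher without T-ALL mouse 3. At its measured promoter Notch1, mutated in many T-cell leukaemias, had 0.514% ± 0.108 (SD, n = 3) in T-ALL and 0.186% ± 0.207 (SD, n = 3) in thymocytes (adjusted p = 0.438). At promoter 1 of 2, Cdkn2a had 4.05% ± 3.92 and 2.11% ± 0.579 in the same libraries (adjusted p = 0.589). Kit (5, 75969941 to 75971980), measured at promoter 1 of 5, had 4.64% ± 6.54 and 0.200% ± 0.347 (adjusted p = 0.297). Hoxa9 had 16.5% ± 10.8 and 2.49% ± 0.329 at its first promoter (adjusted p = 0.0877). At the second Hoxa9 promoter the values were 25.3% ± 21.9 and 26.8% ± 3.97 (adjusted p = 0.960).

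Limma called 1324 promoters higher and 32 lower in T-ALL. Without thymocyte library 1 the model called 678 promoters higher and 10 lower, without library 2 it called 703 higher, without library 3 it called 13 lower, and without T-ALL mouse 2 it called 42 lower. Of the 36 called promoters that the rule named for T-ALL, 17 lost their call without at least 1 single library, among them Nkx6-1, Isl1, Fcgr3, Fgd5, Plagl1, Wt1, the promoters of Ank1 and the weaker promoters of Mecom and Grb10.

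**Figure D3:**
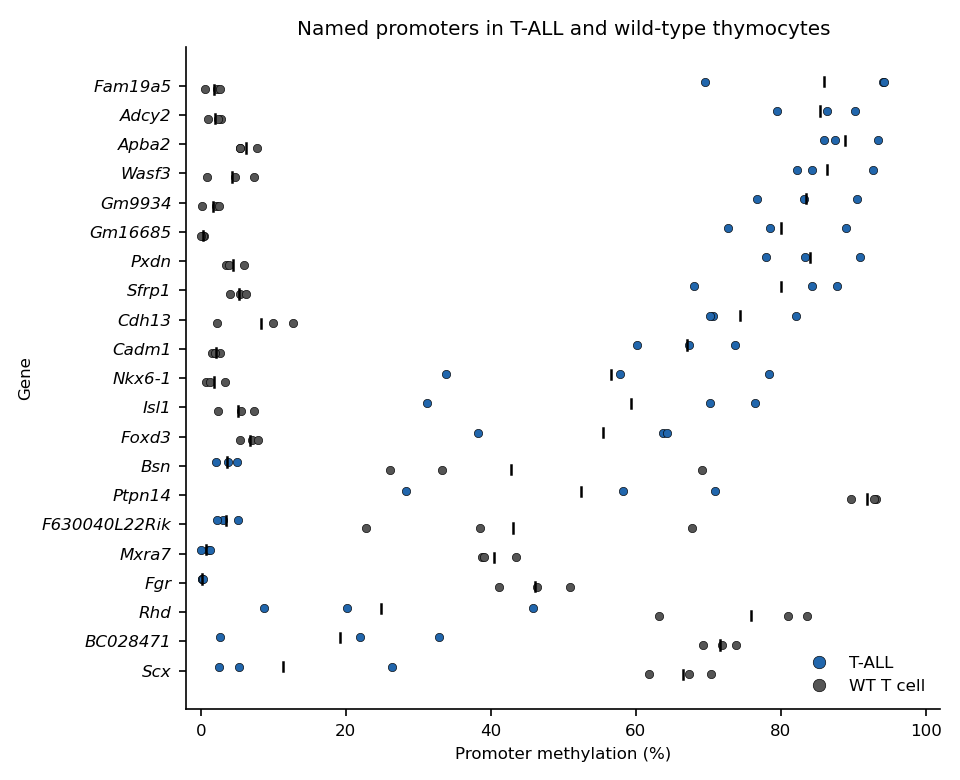
Promoter methylation (%, horizontal axis) of named genes (vertical axis) in the 3 T-ALL mice and 3 wild-type thymocyte libraries. Points are libraries and vertical ticks the group means; Adcy2 has a mean of 85.3% in T-ALL and 2.03% in thymocytes, and Fgr 0.194% and 46.2%.

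The change from the matched control was compared between AML and T-ALL by an interaction term. Over 24520 tiles the AML effect was lower than the T-ALL effect at 225 tiles and higher at 7. At the 225 tiles the mean AML difference from LSK cells was -3.66 points and the mean T-ALL difference from thymocytes 48.9 points. At the 7 tiles they were -8.84 and -47.4 points. A term for the deposit batch gave 359 and 10 tiles and limma 787 and 10, while the first batch alone gave 0 and 0 and the omission of AML mouse 2 gave 138 and 4, both fits chosen after the data were seen. For the mean level the AML effect minus the T-ALL effect was -9.20 points (exact permutation p = 0.00714), and -14.1 and -3.02 points within the first and the second deposit batch. The permutations shuffled libraries within each contrast and across batches, so this p is against no change in either disease. A change in a single disease can make it small, and it does not test whether the changes are equal.

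Granulocytes, the mature myeloid control, had lower methylation in CpG-poor tiles than LSK cells, at 48.4% ± 6.57 (SD, n = 2) and 62.2% ± 1.21 (SD, n = 3). Among 25620 tiles 0 were called by the model and by limma (1113 lower and 6 higher at an unadjusted p under 0.05; limma, 1227 and 6). With the transplant control as a block, which pairs libraries of the same animal, 489 tiles were called lower and 4 higher. This fit rests on 2 pairs, since the LSK library of control 3 had no granulocyte partner. The paired libraries deviated together very little (correlations of 0.009 and 0.031), so these counts are weak evidence of a difference. Without granulocyte library 1 or 2 the counts of lower tiles were 359 and 116, and the lone remaining library was then assumed to vary like the LSK libraries. Thymocytes and LSK cells had 7 lower and 7 higher tiles among 28958 (limma, 0 and 0, with 167 and 211 at an unadjusted p under 0.05), and 67 and 83 with the transplant control as a block. Their groups did not overlap in 14.1% of tiles, where chance gives 10%, and leaving out any of the 6 libraries gave at most 4 lower and 2 higher tiles.

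Against granulocytes, AML marrow had 0 called tiles among 34262 (85 lower and 146 higher at an unadjusted p under 0.05; limma called 0, with 96 and 277). MDS marrow likewise had 0 among 37381 (174 lower and 538 higher; limma called 0, with 186 and 737). Mean levels differed from granulocytes by 1.06 points in AML (exact permutation p = 0.933) and 1.19 in MDS (exact permutation p = 0.667), where the smallest possible p was 0.133. Promoter tests of AML and MDS against granulocytes, of AML against MDS and between wild-type cell types called 0 regions in each comparison. At an unadjusted p under 0.05 they gave 4 lower and 5 higher, 5 and 50, 0 and 1, 9 and 12 (thymocytes against LSK cells), and 75 and 0 (granulocytes against LSK cells), and no other tool was run on them.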

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

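The tests of incomplete conversion, of the deposit batch, of genotype without regard to cell type, of splits within the deposit batches and by whether they mix T-ALL with thymocytes, and of wild-type-like granulocytes as the whole cause were chosen only after the result was seen, as were the first batch alone and the omission of AML mouse 2 for the difference between AML and T-ALL.

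The change from the matched wild-type control differed between AML and T-ALL at 232 tiles by an interaction term and by -9.195 points in mean level, and this difference between groups drew attention to both. The exact permutation test of the mean level is against no change in either disease, so it does not decide whether the changes differ. Of 100 drawn splits of the libraries within each contrast, 7 gave as many tiles, the real one included (highest other, 684), but the other 6 all kept T-ALL and thymocytes apart, and the 85 that mixed them gave at most 1 tile. The splits therefore follow the change in T-ALL and do not decide about chance. The highest set AML mice 3 and 4 and LSK libraries 1 and 4 against the rest, so apart from LSK library 1 it also follows the deposit batch of the marrow libraries. With the first batch alone 0 tiles were called.

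Lower methylation in AML and MDS marrow than in LSK cells may come from mature myeloid cells in whole marrow, since granulocytes also lie low in CpG-poor DNA. Over tiles alike in granulocytes and thymocytes, MDS lay -9.974 points from LSK cells (SD 2.24, mice between -6.69 and -11.5) where granulocytes lay at -1.55. The MDS mice met the bound set against wild-type-like granulocytes as the whole cause. These tiles were chosen by the level of the same granulocyte libraries, which keeps the granulocyte difference small, so the comparison does not decide about that cause. In MDS 482 lower tiles with a batch term argue against the deposit batch as the whole source of the calls. The MDS gap in mean level still differed between batches, at -7.37 and -3.24 points within the first and the second, which held 1 LSK library. In AML the difference over the alike tiles was -9.483 points with mice from -2.78 to -23.1 (SD 9.34). The AML gap in mean level was -9.10 and -1.77 points within the first and the second batch, which leaves granulocytes and the batch open in AML. The loss was 1.891 times as large in AML, and 1.713 times in MDS, over tiles that are lower in granulocytes, between the bounds set beforehand, so a part played by mature cells cannot be told apart from a general loss. Genotype, disease and the contrast of whole marrow with sorted cells also stay open, untested, because the design does not separate them.

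Higher methylation of CpG-dense tiles in T-ALL is the pattern with the most calls. Incomplete conversion is argued against by methylation outside CpG, where the highest T-ALL library exceeded the highest thymocyte library by 0.0209 points. Stem and progenitor cells or granulocytes in the thymus are argued against by their own level in these tiles, at most 8.185% against 52.3% in T-ALL, and the conversion kit of T-ALL mouse 2 by 2290 higher tiles with the replicate of the usual kit alone. The Dnmt3a-null genotype without regard to cell type is argued against by AML and MDS marrow, at most 10.239% in these tiles. Disease, genotype within thymus cells and the thymocyte stage of the leukaemic cells stay open, untested, and each could account for the pattern.

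Other splits of the same libraries tested the remaining counts. A real count of 0 is reached by all 35 splits by construction, so the splits test nothing for the tiles and promoters of AML against LSK cells (highest other, 2 and 1), the promoters of MDS against LSK cells (highest other, 0) or the tiles of AML against MDS. For MDS against LSK cells 1 of 35 splits, the real one, gave 273 tiles, with 0 as the highest other. That share is under 0.05 and the smallest that 35 splits allow, and it was not corrected for the other split tests. It argues against chance for that count only if the deposit batches are set aside, and the count itself was fragile to single libraries and to the tool. Within the batches 18 splits were possible, too few for a share under 0.05 (273 tiles; highest other, 0). Splits were too few for T-ALL against thymocytes (2767 tiles and 1186 promoters; highest other, 0 and 0; 1 of 10 splits) and for thymocytes against LSK cells (14 tiles; highest other, 0; 1 of 10). For AML against MDS the highest split, with 1604 tiles, was that of the deposit batches, mice 1 and 2 of each disease against mice 3 and 4. That split points to a structure of the samples, and within the first and the second batch AML and MDS had 0 called tiles.

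The ETP library, which no comparison used, had 737 tiles at least 20 points below every thymocyte library, where single thymocyte libraries had between 1 and 69 below the others. On the X chromosome, which was outside the comparisons, 26 of 729 tiles were called higher and 2 lower in T-ALL. The labels give no sex. On the Y chromosome T-ALL mouse 1 had 59 CpGs, AML mouse 1 56, MDS mice 1 and 2 54 and 64, and ETP 26. The other AML, MDS and T-ALL libraries had 224 to 329, LSK libraries 182 to 288, thymocyte libraries 213 to 326 and granulocyte libraries 236 and 130. These counts were not weighed against depth or against reads on the X chromosome, so they do not settle the sex of a mouse. A difference in sex between the groups was not tested in any comparison.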

How the results depend on the processing

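Fits chosen only after the data were seen were the batch fits of AML against MDS and, for the difference between AML and T-ALL, the first batch alone and the omission of AML mouse 2. Differences of mean level kept their direction under all 15, 15 and 14 alternatives for AML, MDS and T-ALL, between -2.862 and -9.386 points (AML), -4.505 and -9.227 (MDS) and 1.217 and 8.432 (T-ALL). Exact p-values ran from 0.0571 to 0.571, 0.0571 to 0.457 and 0.1 to 0.6, and no design could reach 0.05. No result set against these alternatives reversed, but other mean levels were not set against them. Some of those differences changed sign within the deposit batches. Within the first and the second batch, AML minus MDS was -1.73 and 1.47 points, and thymocytes minus LSK cells -0.374 and 2.36. The last value compares 1 thymocyte library with 1 LSK library. Within the first batch AML and MDS lay -2.52 and -0.793 points from granulocytes, against 1.06 and 1.19 over all libraries. Calls of all 6 named MDS tiles, of 1 of 10 T-ALL tiles and of 17 of 36 T-ALL promoters were lost in at least 1 setting. Where counts moved by over 1.5 times, the cause was not tested.

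For MDS against LSK cells, tiles called lower were 87 with at least 20 reads, 0 with at least 5 CpGs, 638 with tiles of 1000 bp, 577 (2 higher) at 10 points, 96 at 30 points, 0 (0 higher) at an adjusted p under 0.01, 482 (2 higher) with a batch term, 1018 (8 higher) in the first batch alone, 466 (3 higher) with a replicate block, 1004 by limma and 0 (0 higher) by edgeR, and a rho of 0 gave 2 higher. Limma called 3 promoters lower. Without single libraries there were 0 to 764 lower and 0 to 6 higher tiles. For AML against LSK cells, the first batch alone gave 2 lower tiles and the replicate block 134 lower and 1 higher. The replicate numbers did not pair these libraries: 1 of 3 AML, 2 of 3 MDS and 1 of 3 T-ALL pairs correlated best with their own number.

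For T-ALL against thymocytes, lower and higher tiles were 196 and 1521 with at least 20 reads and 122 and 945 at an adjusted p under 0.01. Lower tiles were 92 with at least 5 CpGs and 188 in the first batch alone, and lower promoters 12 with 500 bp either side. Without single libraries there were 143 to 607 lower and 779 to 3037 higher tiles, and 10 to 42 lower and 678 to 1371 higher promoters. The difference between AML and T-ALL had 359 lower tiles with a batch term, 0 lower and 0 higher in the first batch alone, 787 lower by limma, and 138 lower and 4 higher without AML mouse 2.

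Against granulocytes, AML had 1 lower tile with at least 5 reads, and 0 to 1 lower and 0 to 4 higher without single libraries. For thymocytes against LSK cells, the replicate block by transplant control gave 67 lower and 83 higher tiles, limma 0 and 0, and single omissions 0 to 4 lower and 0 to 2 higher. For granulocytes against LSK cells, that block gave 489 lower and 4 higher tiles, at least 5 reads 2 lower, and single omissions 0 to 359 lower and 0 to 2 higher. No other count of a comparison moved by over 1.5 times with a block. Depth limits the mean levels to CpGs with at least 10 reads in every library except ETP, 169863 of the 1340796 CpGs seen in any library.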

Other observations

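The tile sets described here were chosen by their calls, and no further test was run on them after these values were seen.

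Tiles that fell in MDS were also lower in mature granulocytes than in the other wild-type cells. Over the 272 tiles, or those of them covered, LSK libraries had 86.9% to 89.96% methylation and MDS mice 53.4% to 64.8%. The granulocyte libraries had 66.5% and 47.7%, AML mice 37.6% to 73.7%, T-ALL mice 67.4% to 77.5% and thymocyte libraries 82.3% to 87.0%. Tiles that fell in T-ALL had 18.95% to 24.7% in T-ALL mice and 59.4% to 67.2% in thymocytes. At these tiles the LSK libraries had 54.5% to 61.8%, granulocytes 46.4% and 31.8%, AML mice 22.9% to 49.1% and MDS mice 26.3% to 49.5%.

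The ETP mouse had a mean level of 5.42% over 83124 CpGs, against 8.49% to 10.5% in thymocyte libraries, 8.75% to 9.28% in LSK libraries and 11.9% to 14.5% in T-ALL mice. Over 17831 shared tiles, mostly CpG-dense with a median of 34 CpGs, ETP had 4.2% and thymocytes 6.50% ± 0.818 (SD, n = 3). In 106 tiles ETP lay at least 20 points above every thymocyte library, where single thymocyte libraries had 8 to 185 such tiles.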
